A study of Homo sapiens with 12 samples.

How the data were processed

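Single-channel Agilent arrays were hybridised with labelled cDNA from HEK293T cells in 4 groups of 3 arrays: a plasmid coding for shRNA against Daxx, its luciferase shRNA control, siRNA against HOTAIR, and its GFP siRNA control. Per the labels, RNA was taken 72 h after transfection, and 15 µg of total RNA was labelled with a fluorescent dye. The deposited array files hold the intensity of each spot, as a background-subtracted and detrended signal and as the median brightness of the spot and its surroundings, not scaled between arrays. The genome build was hg19 (GRCh37) per the file headers, which name Feature Extraction 10.5.1.1, whereas the submitters' processing notes name 10.7.3.1. A deposited table of all samples holds log2 values of the same arrays, which differ from the values computed here by a constant per array (0.17 to 0.32, SD over 42405 probes 3.6e-07 to 4.2e-07, r = 1). Its medians were -2.32 to -2.85, its scale is log2, its genes are not centred, and the direction is that of signal.

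Each array held 62976 features, of which 58717 were non-control spots, and 328 to 538 of the non-control spots were marked as outliers by the software and left out. The processed signal was divided by its 75th percentile on the array and taken to log2, and replicate spots of a probe were averaged. The median coefficient of variation of replicate spots was 8.99% and 8.14% on the arrays of slide 1 and 5.15% to 5.98% on the other arrays. Of 42405 probes, 24910 could be given a gene name through their accession, from a gene table of assembly GRCh38.p14 used for names alone, and 8263 of the probes stand for lincRNA regions. Probes were kept when well above background on all 3 arrays of at least 1 group, and each gene name was represented by its probe with the highest mean over the 12 arrays. Signal over background sets the depth of these data, and the number of arrays limits their precision.

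Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means of all 12 arrays), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The comparisons were Daxx shRNA against luciferase shRNA, HOTAIR siRNA against GFP siRNA, and the difference between these responses. All p-values measure only the spread between these samples. DAXX and HOTAIR were also tested with exact permutation tests. Lists of genes, 35 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 70 tests of both comparisons, and for the difference over the 35 lists. Camera with an estimated correlation and fry stood beside it, and fry tests whether a list moves one way without comparing it with other genes. Of 821 listed genes, 796 have a probe. The lists, the test and the choice of genes to name were fixed before the data were examined.

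The genes named are the targeted gene and, among gene symbols past the threshold with all 3 knockdown arrays beyond all 3 controls, the 10 largest rises and 10 largest falls. Where fewer than 10 pass, those with the smallest unadjusted p fill up to 5 in each direction, and are said not to pass. From each list come at most 4 members with the smallest p, and for the difference the 5 largest in each direction past 0.05. Other genes are said to have been chosen after their values were seen. Where no control array was well above background, the fold is given as a lower bound at the 75th-percentile scaling, which another scaling or background correction can undercut.

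The labels name each control as the control of the same-numbered knockdown, so the experiment and replicate number form the replicate block. As a check, the arrays' deviations from their group means were correlated across genes within each same-numbered pair. This gave r = 0.959, 0.863 and 0.859 for the Daxx pairs, where the highest r with an array of another number was -0.859, 0.779 and 0.779, and r = 0.407, 0.192 and 0.0830 for the HOTAIR pairs, where it was -0.168, 0.128 and 0.128. The third HOTAIR pair was thus no more alike than arrays of different numbers. The arrays lie on 3 slides: Daxx pair 1 on slide 1, Daxx pairs 2 and 3 on slide 2 and the HOTAIR experiment on slide 3, and the scan sessions follow the slides. Deviations from a mean of 3 arrays sum to 0, so a shift of slide 1 alone gives a high r within each Daxx pair and the -0.859. For the Daxx pairs only the margin of pairs 2 and 3 over 0.779 thus bears on the pairing. Between the experiments, slide and delivery cannot be told apart.

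On simulated changes added to 200 of 28255 genes, the test without the block recovered 3% and 0% of changes of 1 on the log2 scale in the Daxx and HOTAIR comparisons, and 33% and 31% of changes of 2, with 0 false calls. With the replicate block it recovered 62% and 61%, and 93% and 90%, with 16 and 8 false calls. The simulated arrays took their pair means and their spread from the fit with the replicate block, in both experiments. A gain with the block was thus favoured by the setting and does not show which test suits the real arrays. A list of 25 genes shifted by 0.3 was recovered, and 0 of 20 unshifted lists were called. The simulated spread was drawn independently for each gene, so this does not show how often lists of correlated genes are called wrongly.

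The alternatives were quantile normalization, scaling by the array's median, normexp background correction with an offset of 50 on the median signal (the files hold no mean signal), no filter, a filter on all 12 arrays, the mean over probes, each probe on its own, the authors' values, the 6 arrays of a comparison alone, trend and robust eBayes, array weights, a fold of at least 2, the replicate block, the slide as a block, and leaving out each array. Chosen after seeing the data were leaving out Daxx pair 1, the replicate block with trend and robust, the replicate block at an adjusted p under 0.1, and array weights by limma's gene-by-gene method. Control spots were left out of the tests. Some of the genes that the naming rule takes are not reported here. The data.table package, version 1.17.8, handled the values, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.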

Results

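RNA levels were measured across the genome in HEK293T cells, a human embryonic kidney line that carries the large T antigen of a simian virus, after depletion of Daxx or of HOTAIR. Daxx is a chaperone of histone H3.3 and a regulator of transcription and apoptosis, and HOTAIR is a long non-coding RNA from the HOXC locus that is known for binding chromatin-modifying complexes. A plasmid coding for a short hairpin RNA against Daxx was compared with one against luciferase, and siRNA against HOTAIR with siRNA against GFP, each at 3 days after transfection. Each of the 4 groups held 3 arrays, and each knockdown array had a control array of the same replicate number. On the 12 arrays, 74.6% to 89.3% of 58717 non-control spots were well above background, and 0 spots were saturated. The 75th percentile of the processed signal was 1620 to 4389, and 28311 gene names, 16540 of them gene symbols, were tested. The number of arrays, 3 per group, limits the precision. Arrays of the same group correlated across genes at r = 0.829 to 0.991 (12 pairs) and arrays of different groups at r = 0.834 to 0.993 (54 pairs), where genes are not independent replicates. Both arrays of Daxx pair 1, which shared a slide of their own, stood apart from the rest. Between the mean of pair 1 and that of pairs 2 and 3, 49.5% of genes differed by over 1 on the log2 scale, against 2.57% between pair 2 and pair 3.

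The first question was whether each targeted RNA was lower where the labels say it was targeted. DAXX, on chromosome 6, was at 40.4% of its control level after Daxx knockdown, and HOTAIR, on chromosome 12, at 42.1% after HOTAIR knockdown. The log2 level of DAXX was 2.36 ± 0.78 (SD, n = 3) with luciferase shRNA and 1.05 ± 0.62 (SD, n = 3) with Daxx shRNA, a difference of -1.31 (SE 0.40). The pairs gave 32.9%, 36.7% and 54.7% of the control level. The log2 level of HOTAIR was -1.16 ± 0.04 (SD, n = 3) with GFP siRNA and -2.41 ± 0.13 (SD, n = 3) with HOTAIR siRNA, a difference of -1.25 (SE 0.30), and its pairs gave 37.5%, 46.4% and 42.8%. For both targets all 3 knockdown arrays lay below all 3 controls, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. In the other experiment neither target differed by more than the spread between replicates. DAXX was at 107% of its control after HOTAIR knockdown (exact permutation p = 0.4), and HOTAIR at 108% after Daxx knockdown (exact permutation p = 0.7). Adjusted over all genes, the limma p was 1.0 for both targets. With the slide as a block it was 0.0457 for DAXX and 0.0384 for HOTAIR, where all arrays of the HOTAIR experiment share 1 slide and the block changes only the estimate of the spread. Over all alternatives it ranged from 0.00986 to 1.0 for DAXX and from 0.00108 to 1.0 for HOTAIR. Leaving out pair 1, which lies on slide 1, gave a DAXX difference of -1.16 (adjusted p = 0.450), and pair 1 alone gave -1.60.

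**Figure D1:**
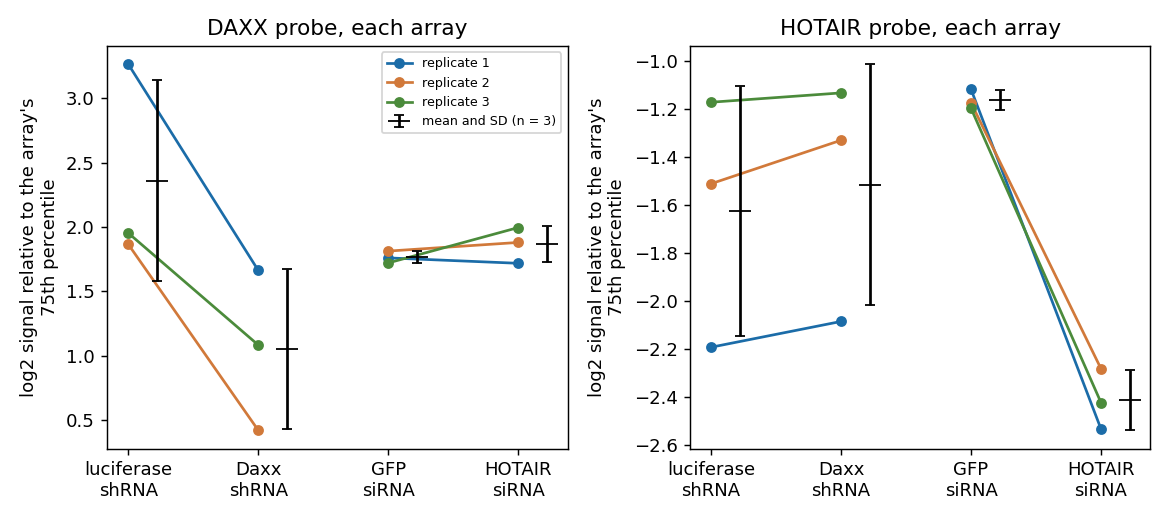
Log2 signal of the DAXX probe (left) and the HOTAIR probe (right) on each of the 12 arrays, relative to the array's 75th percentile, by group. Each point is an array: the 3 Daxx shRNA arrays lie below the 3 luciferase arrays for DAXX, and the 3 HOTAIR siRNA arrays below the 3 GFP arrays for HOTAIR.

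The Daxx comparison asks which genes responded to loss of Daxx. Groups of genes known for responses to stress and to mitogens were higher with Daxx shRNA than with luciferase shRNA: p53 targets, immediate early genes, heat shock genes, genes of the unfolded protein response, and autophagy and lysosome genes. Their median log2 differences lay between 0.14 and 0.33, each past the threshold at the preset correlation (adjusted p from 3.2e-09 to 0.00669) and none with an estimated correlation (adjusted p from 0.0737 to 0.573). No single gene passed the threshold: limma called 0 of 28311 genes, with 574 at an unadjusted p under 0.05, and with the replicate block also 0, with 3952. These are 2.03% and 14.0% of the genes, where p-values without any change would give 5%. Genes are not independent, so neither share was tested against 5%. Blocking by slide, it called 17 genes, 5 higher and 12 lower, DAXX among the latter. For 1188 genes (4.2%) the groups did not overlap, where chance gives 10% if the 6 arrays are alike apart from their group, which those of pair 1 are not, so that the share cannot be held against 10%. Daxx pair 1, which stood apart on slide 1, took part in every one of these differences.

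Among gene symbols with the smallest p, CXCL10, a chemokine gene induced by interferons, was at least 3.47-fold higher at the 75th-percentile scaling, as it was not well above background on any of the 3 luciferase arrays. Its log2 difference was 2.39 (SE 0.41, n = 3 per group), and its pairs gave 1.39, 2.86 and 2.91. A further CXCL10 probe was not well above background on any of these 6 arrays. Over the scalings, with the normexp background correction among them, the log2 difference of CXCL10 ranged from 0.64 to 2.40, so the bound does not hold under each. CXCL10 passed in limma without pair 1 (2.89, adjusted p = 0.0346), without luciferase replicate 1 (2.94, adjusted p = 0.0170) and with the slide as a block (adjusted p = 0.0440), and its adjusted p ranged from 4.6e-04 to 1.0 over all alternatives. DQX1, a gene named for its helicase domain, was at least 3.70-fold higher at the same scaling, with 0 of 3 luciferase arrays well above background, and its log2 difference ranged from 0.76 to 1.90 over the scalings. ANXA1, which codes for a membrane-binding annexin, differed by 1.30 (SE 0.25, n = 3 per group), GALNT8, a glycosyltransferase gene, by 1.20 (SE 0.26), and M6PR, a sorting receptor for lysosomal enzymes, by 1.03 (SE 0.19). Lower values were found for ITM2C, a transmembrane protein gene, at -1.0 (SE 0.17), for CHIC2 at -0.88 (SE 0.17), and for DIXDC1, a gene of Wnt signalling, at -0.84 (SE 0.19). RASSF3, of a family with Ras association domains, gave -0.82 (SE 0.15) and HABP4 -0.77 (SE 0.16). None of these 10 genes passed the threshold over all genes. For each of them all 3 pairs had the same sign and the groups did not overlap, which picking by the smallest p favours. With the slide as a block RASSF3 and ITM2C after Daxx knockdown also passed (adjusted p = 0.0440 for both), and over all alternatives their adjusted p ranged from 0.00608 to 1.0 and from 0.00419 to 1.0. All 10 passed with the planned array weights, which stopped before converging and called 727 genes, and all but DQX1 with the replicate block, trend and robust.

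The p53 targets, genes known to be switched on by the tumour suppressor p53, had a median log2 difference of 0.30, with 21 of 25 measured members higher and 4 lower. The activity of p53 itself in these cells was not measured. Their camera test gave an adjusted p of 3.2e-09, and adjusted p = 0.0737 with an estimated correlation. TP53I3, an oxidoreductase gene, differed by 0.89 (SE 0.33, n = 3 per group), BTG2, an antiproliferative gene, by 0.69 (SE 0.19), TNFRSF10B, which codes for a death receptor, by 0.62 (SE 0.19) and FDXR by 0.55 (SE 0.23). The list's medians were 0.37 in pair 1 on slide 1 and 0.25 and 0.21 in pairs 2 and 3 on slide 2. The adjusted p was 6.1e-07 with the slide as a block and 0.00205 without pair 1. It ranged from 1.1e-10 to 0.110 over all alternatives, taken one at a time. By camera with the replicate block and an estimated correlation together, it was 0.672 for the p53 targets. Immediate early genes, transcription factors and phosphatases that respond quickly to growth signals, had a median of 0.33, with 20 of 25 members higher and 5 lower. The list test gave adjusted p = 3.5e-07, and adjusted p = 0.336 with an estimated correlation. The transcription factor genes EGR1, FOS, EGR3 and FOSL1 differed by 1.28 (SE 0.42), 1.20 (SE 0.35), 0.97 (SE 0.39) and 0.74 (SE 0.29). The pairs gave list medians of 0.24, 0.38 and 0.34, and the adjusted p was 1.3e-04 with the slide as a block and 9.97e-04 without pair 1. It ranged from 7.4e-09 to 0.715 over all alternatives. Adjusted over the list alone, limma called 0 members of either list. With the replicate block it called 7 of the p53 targets, all higher, and 14 immediate early genes, 12 higher and 2 lower, again adjusted over the list alone.

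**Figure D2:**
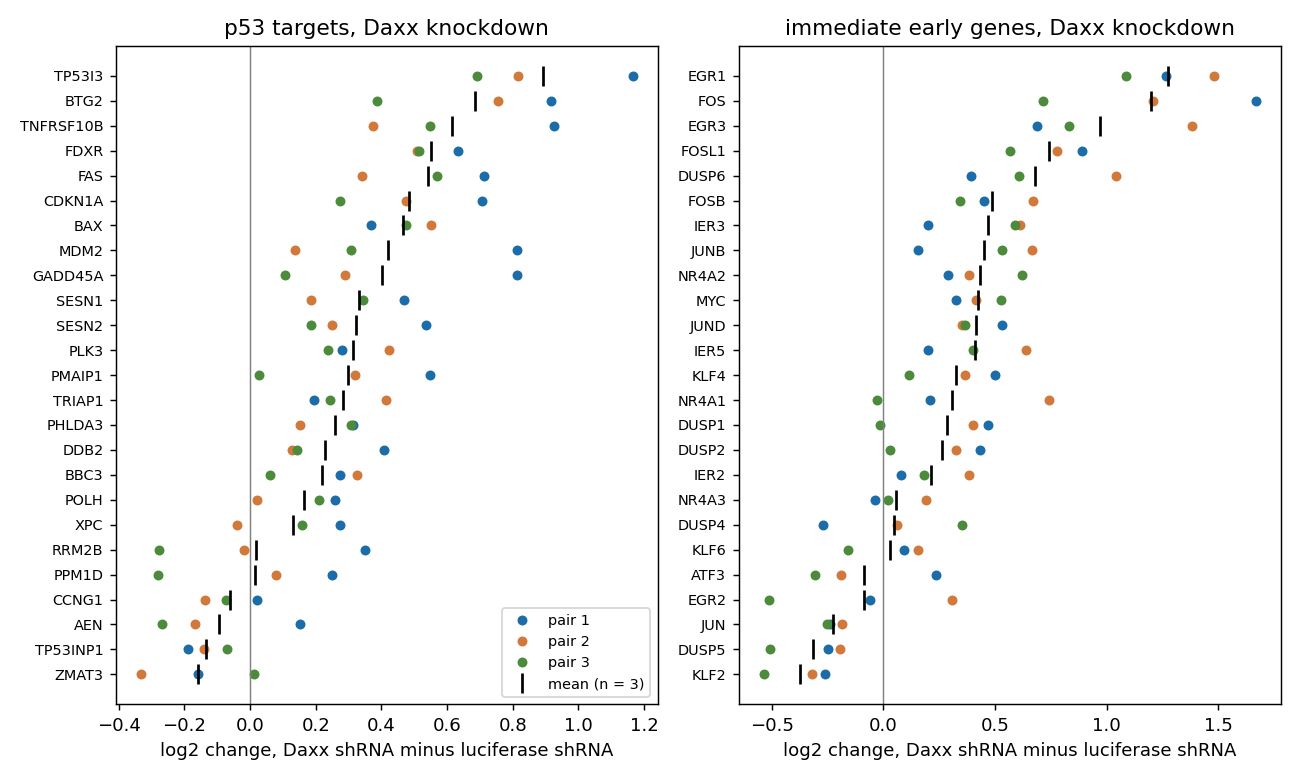
Log2 change, Daxx shRNA minus luciferase shRNA, of every measured p53 target (left) and immediate early gene (right), with a point for each of the 3 pairs and a bar for the mean (n = 3). Of the 25 members each, 21 p53 targets and 20 immediate early genes have a mean above 0.

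Heat shock genes, which code for chaperones and co-chaperones, had a median log2 difference of 0.21 after Daxx knockdown, with 15 of 20 members higher and 5 lower. The test of the list gave adjusted p = 7.2e-05, and adjusted p = 0.240 with an estimated correlation. HSPA1A and HSPA1B, inducible chaperone genes with nearly the same sequence, differed by 1.47 (SE 0.45, n = 3 per group) and 0.73 (SE 0.27), and the co-chaperone genes DNAJB1 and DNAJB4 by 0.71 (SE 0.32) and 0.60 (SE 0.32). The pairs gave list medians of 0.29, 0.44 and -0.03, so pair 3 did not share the direction. The call was lost without luciferase replicate 1 (adjusted p = 0.284) or Daxx replicate 2 (adjusted p = 0.0937). Genes of the unfolded protein response, which acts in the endoplasmic reticulum, had a median of 0.20, with 20 of 23 members higher and 3 lower. For this list the test gave adjusted p = 5.8e-04, and adjusted p = 0.573 with an estimated correlation. MANF differed by 0.50 (SE 0.23), HYOU1 by 0.38 (SE 0.21), HSP90B1 by 0.24 (SE 0.15) and PDIA6 by -0.30 (SE 0.17). The pairs gave 0.36, 0.18 and 0.12, and the call was lost without luciferase replicate 1 (adjusted p = 0.749) or Daxx replicate 2 (adjusted p = 0.165). For autophagy and lysosome genes after Daxx knockdown the median was 0.14, with 20 of 26 measured members higher and 6 lower. Their adjusted p was 0.00669, and adjusted p = 0.240 with an estimated correlation. WIPI1, a gene of autophagosome formation, differed by 0.66 (SE 0.33), ATG16L1 by 0.29 (SE 0.17), BECN1 by 0.28 (SE 0.16) and GABARAP by 0.25 (SE 0.16). The pairs gave 0.10, 0.19 and 0.11. This call was lost without luciferase replicate 1 (adjusted p = 0.405), Daxx replicate 1 (adjusted p = 0.0573) or Daxx replicate 2 (adjusted p = 0.166), with the mean over probes (0.12, adjusted p = 0.0514), and without pair 1 (adjusted p = 0.0937), where the median was 0.13 with fewer arrays. With the slide as a block the adjusted p was 2.1e-04, 2.1e-04 and 0.0120 for the 3 lists in this order, and without pair 1 it was 0.00360 for heat shock and 0.0215 for the unfolded protein response. Over all alternatives it ranged from 2.1e-08 to 0.481 for heat shock, from 1.5e-05 to 0.996 for the unfolded protein response and from 0.00267 to 0.481 for autophagy. By camera with the replicate block and an estimated correlation together, it was 0.898 for heat shock and 0.672 for each of the others. Adjusted over the list alone, limma with the replicate block called 6 heat shock genes and 4 genes of the unfolded protein response, all higher, and without it 0.

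S phase genes, which act in DNA replication, had a median log2 difference of -0.07 after Daxx knockdown, with 25 of 35 members lower and 10 higher. Their pairs gave 0.01, -0.11 and -0.16. For the S phase genes after Daxx knockdown the adjusted p was 0.0578, with the replicate block 0.0465 and without pair 1 0.00205, which both change the call, and with the slide as a block 0.0928. With an estimated correlation the adjusted p was 0.982. EXO1, an exonuclease gene, differed by -0.41 (SE 0.17, n = 3 per group). Daxx partners and H3.3 chaperones had a median of -0.02 over 22 measured members (adjusted p = 0.927), and the Daxx partner gene ATRX differed by 0.28 (SE 0.23). Interferon-stimulated genes had a median of 0.01 over 33 measured members (adjusted p = 0.761), and CXCL10 was the 1 member past the threshold when adjusted over the list alone. Markers of blood cells had a median of -0.13 over 9 measured members (adjusted p = 0.867), and CD68, a lysosomal gene of macrophages, was the 1 member past it, at -0.93 (SE 0.24), when adjusted over the list alone. Among the lists for growth and survival, medians were 0.14 for NF-kB targets, 0.01 for apoptosis regulators, -0.08 for Wnt (TCF) targets, 0.05 for glucocorticoid receptor targets, -0.00 for TGF-beta targets and EMT genes and 0.04 for integrated stress response genes, with adjusted p from 0.0901 to 0.999. For chromatin and development, medians were -0.21 for the HOXA cluster, -0.02 for HOXB, -0.01 for HOXC, -0.02 for HOXD, -0.09 for genes reported as repressed through HOTAIR, 0.08 for PRC2 subunits, 0.03 for PRC1 subunits, 0.02 for LSD1, CoREST and REST, -0.17 for clustered protocadherins and 0.13 for cancer testis genes, with adjusted p from 0.253 to 0.999. For growth machinery, medians were -0.13 for replication-dependent histones, -0.00 for mitosis genes, 0.01 for ribosomal proteins, -0.03 for oxidative phosphorylation, 0.01 for hypoxia and glycolysis, 0.02 for cholesterol synthesis and 0.05 for the RNA interference machinery, with adjusted p from 0.103 to 0.980. Medians were -0.03 for markers of fibroblasts, -0.08 for markers of keratin-rich epithelial lines and -0.08 for the neuronal and adrenal lineage genes of HEK293 lines, with adjusted p from 0.377 to 0.744. The mean and the median differed in sign for fibroblasts, TGF-beta targets, integrated stress response genes and HOXD, and the test pointed up for fibroblasts, TGF-beta targets and mitosis genes in spite of a median below 0.

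The HOTAIR comparison asks which genes responded to loss of HOTAIR. Markers of fibroblasts, Wnt targets and ribosomal protein genes were higher with HOTAIR siRNA than with GFP siRNA, by median log2 differences of 0.27, 0.11 and 0.09. Each passed at the preset correlation (adjusted p from 5.4e-04 to 0.0411) and none with an estimated correlation (adjusted p from 0.240 to 1.0). Genes of the HOXD cluster, a locus known for repression through HOTAIR in fibroblasts, did not pass, with a median of -0.09. No single gene passed the threshold: limma called 0 of 28311 genes, with 441 at an unadjusted p under 0.05. This is 1.56% of the genes, and 13.5% with the replicate block, where p-values without any change would give 5%. For 4861 genes (17.2%) the groups did not overlap, where chance gives 10%. Genes are not independent and no spread of this share was computed, so it was not tested against 10%. By limma without a block, another split of the 6 arrays gave 605 genes at an unadjusted p under 0.05. With the replicate block limma called 2 genes, both higher and both named after their values were seen. These were MAP1LC3C, a gene of the autophagy protein LC3 family, at 1.63 (adjusted p = 0.0424), and a lincRNA region on chromosome 4 at 11724168 to 11726750 (hg19), at 2.57 (adjusted p = 0.0385). Blocking by slide, it called 5, also named after their values were seen and each with adjusted p = 0.0384. Lower were HOTAIR and a lincRNA region on chromosome 12 at 54356229 to 54357908 (hg19), reverse strand, where both probes gave -1.09. This region lies at the HOTAIR locus, where reverse-strand probes of other regions, also chosen after their values were seen, gave -0.34 (54356095 to 54362515), -0.45 (54361053 to 54361178) and -0.16 (54361178 to 54362460). Forward-strand probes there gave -0.54 (54361053 to 54361178), -0.83 (54361178 to 54362460, well above background on 8 of 12 arrays), -0.14 (54356229 to 54357908), -0.067 (54359748 to 54359871) and 0.61 (54360060 to 54360161). Higher were HDAC9, a histone deacetylase gene, at 1.24, and lincRNA regions on chromosome 3 at 170179081 to 170184556, at 1.16, and on chromosome 10 at 76945044 to 76950119, at 1.47. HOXC11 and HOXC12, the HOX genes on either side of HOTAIR, gave -0.04 and 0.10.

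Among gene symbols with the smallest p after HOTAIR knockdown, TNMD, which codes for a membrane protein of tendons, was at least 3.49-fold higher, and DIRC3, a non-coding RNA gene, at least 2.43-fold higher, at the 75th-percentile scaling, each with 0 of 3 GFP arrays well above background. Over the scalings, with the normexp background correction among them, their log2 differences ranged from 0.87 to 2.57 and from 0.54 to 1.52. These bounds thus do not hold under each either. SCUBE3, a gene for a secreted protein, differed by 1.60 (SE 0.34, n = 3 per group), with 1 of 3 GFP arrays well above background. ASTN1, a neuronal adhesion gene, differed by 1.24 (SE 0.25) and FLRT1, also an adhesion gene, by 1.12 (SE 0.24). Lower values were found for TMEM106A, at -1.29 (SE 0.24), TCEAL4, at -1.23 (SE 0.27), UGT2B4, a glucuronosyltransferase gene, at -1.04 (SE 0.26), and PPP6R1, a phosphatase subunit gene, at -0.66 (SE 0.15). KCND1, a potassium channel gene, gave -2.11 (SE 0.45), with pairs at -2.28, -2.87 and -1.17. Over the scalings and normexp SCUBE3 fell to 0.78, and TMEM106A, UGT2B4 and KCND1 lay as near to 0 as -0.52, -0.44 and -0.92. The KCND1 spot lies in column 110 of the array, which held 14 of the 38 spots over 2 on the log2 scale below all GFP arrays on HOTAIR siRNA array 1 and 21 of the 23 such spots on array 2, a count chosen after the values were seen. None of these 10 genes passed over all genes. In each all 3 pairs had the same sign, which picking by the smallest p favours. Each passed with array weights of either kind, which called many more genes. The planned weights, which stopped before converging, called 752. Without HOTAIR siRNA replicate 3 limma called 3 genes, UBR4 at -9.08, B3GALT6 at -4.45 and DDX54 at -2.05 (adjusted p 0.00234, 0.00234 and 0.0382), named after their values were seen, and their spots also lie in column 110.

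Markers of fibroblasts had a median log2 difference of 0.27 after HOTAIR knockdown, with 7 of 10 measured members higher and 3 lower. By the list test, adjusted p = 5.4e-04, and adjusted p = 0.501 with an estimated correlation. The collagen gene COL6A3 differed by 1.16 (SE 0.28, n = 3 per group) and was the 1 member past the threshold when adjusted over the list alone. PDGFRA, a growth factor receptor gene, differed by 0.44 (SE 0.18), the collagen gene COL3A1 by 1.42 (SE 0.97) and POSTN, a matrix protein gene, by 0.88 (SE 0.64). Over the scalings and normexp COL6A3 ranged from 0.49 to 1.25, PDGFRA from 0.19 to 0.53, COL3A1 from 0.57 to 1.51 and POSTN from 0.16 to 0.97. COL3A1 and POSTN were each well above background on 1 GFP array and 2 HOTAIR siRNA arrays, and 6 of the 10 members were so on all 12 arrays. Restricted to genes well above background on all 12 arrays, the list's median was 0.12 (adjusted p = 0.168). Its medians by pair were 0.37, 0.23 and 0.22. Wnt targets had a median of 0.11, with 13 of 18 measured members higher and 5 lower. Their adjusted p was 0.0269, and adjusted p = 0.240 with an estimated correlation. WIF1, a secreted Wnt inhibitor gene, differed by 0.57 (SE 0.28), MYC, a growth regulator, by 0.35 (SE 0.30), and RNF43 and NKD1, feedback inhibitors of Wnt signalling, by 0.24 (SE 0.16) and 0.24 (SE 0.22). The pairs gave 0.11, 0.12 and 0.22, and the call was lost without GFP replicate 2 (adjusted p = 0.128), GFP replicate 3 (adjusted p = 0.0519) or HOTAIR siRNA replicate 3 (adjusted p = 0.279).

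The genes of cytosolic ribosomal proteins after HOTAIR knockdown had a median log2 difference of 0.09, with 45 of 48 members higher and 3 lower. Their adjusted p was 0.0411, and adjusted p = 1.0 with an estimated correlation. RPL7, RPL34, RPS28 and RPLP2 differed by 0.26 (SE 0.34), 0.25 (SE 0.33), 0.15 (SE 0.19) and 0.12 (SE 0.17). The pairs gave 0.05, 0.07 and 0.16. The call was lost without GFP replicate 2 (adjusted p = 0.110), GFP replicate 3 (adjusted p = 0.0656) or HOTAIR siRNA replicate 3 (adjusted p = 0.657), and with quantile normalization (median 0.04, adjusted p = 0.702), with each array's median in place of its 75th percentile (0.18, adjusted p = 0.119), with the mean over probes (adjusted p = 0.0593) and with the authors' values (adjusted p = 0.0531). Over all alternatives the adjusted p ranged from 5.5e-05 to 1.0 for ribosomal proteins, from 0.00721 to 0.576 for Wnt targets and from 6.6e-05 to 0.996 for fibroblast markers. By camera with the replicate block and an estimated correlation together, it was 0.898 for ribosomal proteins and 0.672 for each of the others. All arrays of this comparison lie on slide 3, so no within-slide value differs from the comparison itself. With the slide as a block, which changes the spread alone, the adjusted p was 2.1e-04, 0.0269 and 0.00173 for the same 3 lists.

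**Figure D3:**
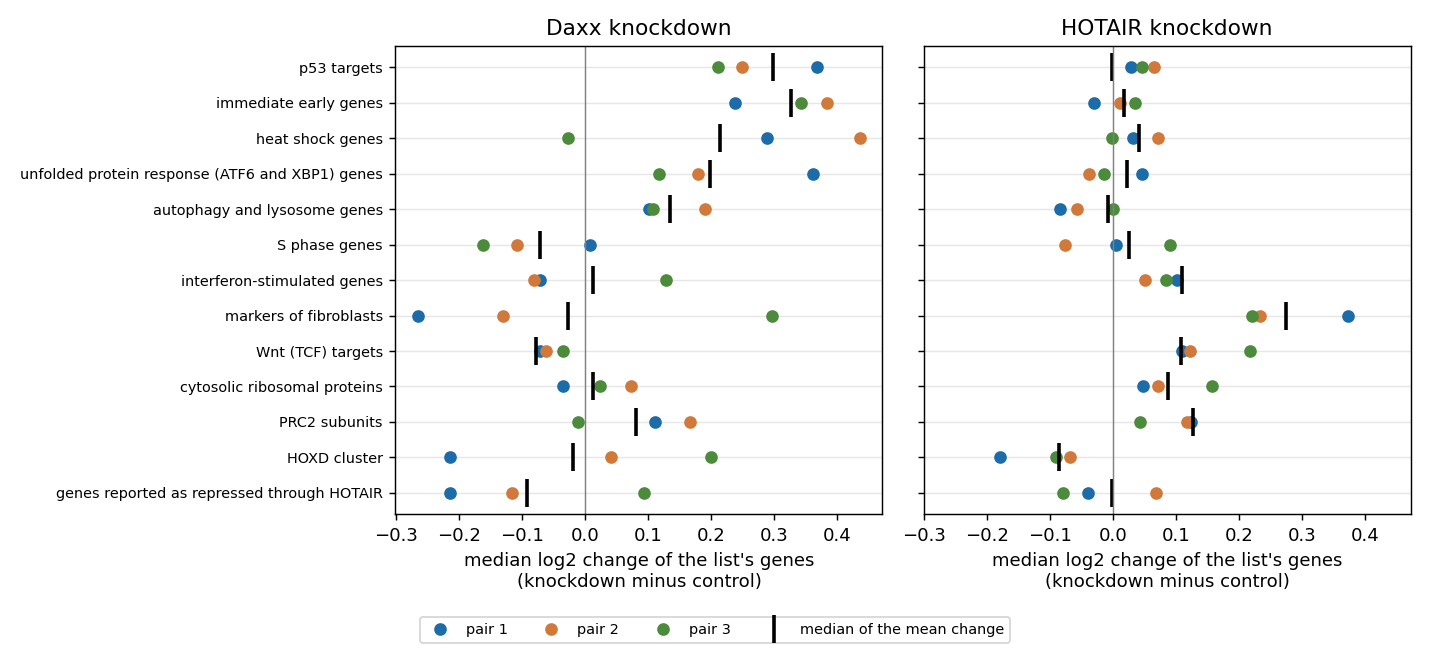
Median log2 change of the genes of 13 lists, knockdown minus control, after Daxx knockdown (left) and HOTAIR knockdown (right). Points are the 3 pairs and bars the median of the mean change, and the p53 targets lie at 0.30 on the left and at -0.00 on the right.

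Genes reported as repressed through HOTAIR had a median log2 difference of -0.00 after HOTAIR knockdown, with 5 of 11 measured members higher and 6 lower (adjusted p = 0.927). Their mean was 0.05, and the test pointed up. HOXD9 and HOXD10 differed by -0.40 (SE 0.22, n = 3 per group) and -0.25 (SE 0.16), and JAM2, an adhesion gene, by 0.41 (SE 0.33). With the replicate block limma called 3 members of this list, all higher, when adjusted over the list alone, and 0 without it. Subunits of PRC2, the complex that methylates histone H3 and is known to bind HOTAIR, had a median of 0.13, with 10 of 10 measured members higher (adjusted p = 0.124). MTF2 and RBBP7 differed by 0.17 (SE 0.16) and 0.17 (SE 0.27). LSD1, CoREST and REST had a median of 0.06 (adjusted p = 0.470). Interferon-stimulated genes had a median of 0.11, with 20 of 33 measured members higher and 13 lower (adjusted p = 0.0569), and DDX60, IFI44L and OAS2 differed by 0.50 (SE 0.20), 1.43 (SE 0.62) and -0.94 (SE 0.46), where IFI44L was well above background on 1 GFP array and 2 HOTAIR siRNA arrays. For development, medians were -0.09 for HOXD, -0.10 for HOXB, -0.06 for HOXA, -0.01 for HOXC, 0.05 for clustered protocadherins, 0.06 for neuronal and adrenal lineage genes and -0.07 for cancer testis genes, with adjusted p from 0.0951 to 0.999. For stress and signalling, medians were -0.00 for p53 targets, 0.02 for immediate early genes, 0.04 for heat shock, 0.02 for the unfolded protein response, 0.01 for the integrated stress response, -0.01 for autophagy, -0.01 for apoptosis regulators, 0.00 for NF-kB targets, 0.05 for glucocorticoid receptor targets and 0.04 for TGF-beta targets and EMT genes, with adjusted p from 0.144 to 0.993. For growth machinery, medians were 0.03 for S phase, 0.02 for mitosis, -0.02 for histones, 0.02 for oxidative phosphorylation, 0.01 for hypoxia and glycolysis, -0.08 for cholesterol synthesis, -0.07 for the RNA interference machinery, 0.01 for PRC1 and 0.06 for Daxx partners and H3.3 chaperones, with adjusted p from 0.287 to 0.927. Markers of blood cells and of keratin-rich epithelial lines had medians of -0.07 and -0.06, with adjusted p of 0.999 and 0.927. Median and mean differed in sign for p53 targets, heat shock, the unfolded protein response, the integrated stress response, keratin-rich lines and cancer testis genes. For p53 targets, apoptosis regulators, keratin-rich lines and HOXC the test pointed up in spite of a median below 0, and for the integrated stress response it pointed down in spite of one above 0.

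A last comparison asks where the responses to loss of Daxx and of HOTAIR differed. The p53 targets and the immediate early genes had the higher response to Daxx knockdown, each by a median log2 difference of 0.27 between the responses, as did heat shock genes, by 0.17. Wnt targets and neuronal and adrenal lineage genes had the higher response to HOTAIR knockdown, with differences of -0.14 and -0.18. Adjusted over the 35 lists, the p was 0.00394 for p53 targets and for immediate early genes, 0.0252 for heat shock, 0.0252 for Wnt targets and 0.0371 for the neuronal and adrenal lineage genes. With an estimated correlation, adjusted p = 0.613 for immediate early genes and 0.392 for each of the other 4. With the replicate block the calls on heat shock (adjusted p = 0.0755) and on neuronal and adrenal lineage genes (adjusted p = 0.0643) were lost, and the unfolded protein response, with a median of 0.22, went from adjusted p = 0.0795 to 0.0238, but with an estimated correlation its adjusted p was 0.882, and 0.945 with the block. With the slide as a block the same calls were lost, at 0.0576 and 0.0598, and the unfolded protein response passed, at 0.0423. Without Daxx pair 1 none of the 5 lists passed, with adjusted p from 0.0792 to 0.257, and the differences were 0.18 for p53 targets, 0.18 for immediate early genes, 0.11 for heat shock, -0.15 for Wnt targets and -0.11 for the neuronal and adrenal lineage genes, with fewer arrays. Within slide 3 there is no Daxx array, so the 2 experiments differ in slide as well as in delivery and target. For no single gene did limma find a difference: 0 of 28311 genes passed, with 522 at an unadjusted p under 0.05, and 4574 with the replicate block, where also 0 passed. These are 1.84% and 16.2% of the genes, where p-values without any change would give 5%. Without HOTAIR siRNA replicate 3, 2 genes passed, UBR4 at 9.29 and B3GALT6 at 4.64 (adjusted p = 0.0232 for both), which are the genes of column 110. Across 28255 genes the responses correlated at r = -0.09 (Spearman's rho -0.09), where genes are not independent replicates. The r between single pairs of the 2 experiments lay between -0.23 and 0.08, and it changed sign without Daxx replicate 1 (0.11), luciferase replicate 2 (0.02) or luciferase replicate 3 (0.10). It was -0.20 without luciferase replicate 1 and -0.19 without Daxx replicate 2. As neither comparison called a gene, the number called in both and the number expected by chance were fixed at 0. They say nothing about shared genes.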

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

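Of the tests in this part, those of a swap, of cells of another type, of Daxx pair 1 alone, of an interferon response and of fibroblasts, and the splits by counts of genes, were chosen after the result was seen. The bound for the interferon response was also changed after its value was known, to ask for members whose median lies below the rise to be explained by more than their SD.

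A difference between the responses to Daxx and HOTAIR knockdown, tested as an interaction over 35 lists, was found for 5 of them. The median Daxx response minus HOTAIR response on the log2 scale was 0.27 for p53 targets (adjusted p = 0.00394), 0.27 for immediate early genes (0.00394), 0.17 for heat shock genes (0.0252), -0.14 for Wnt targets (0.0252) and -0.18 for neuronal and adrenal lineage genes (0.0371). With the replicate block heat shock genes (adjusted p = 0.0755) and neuronal and adrenal lineage genes (0.0643) no longer passed. None of the 5 passed with an estimated correlation (0.392 to 0.613) or without Daxx pair 1 (0.0792 to 0.257), where the differences were 0.18, 0.18, 0.11, -0.15 and -0.11 in the same order with fewer arrays, so that the loss of a call does not by itself show that pair 1 was its source. A signal was present in control spots that the comparisons do not use: on average over the 12 arrays 39.8% of 3360 spike-in spots were well above background, 63.8% on slide 1, 35.8% on slide 2 and 34.5% on slide 3, against at most 2.92% of negative controls.

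Both arrays of Daxx pair 1, which share slide 1, stand apart: 49.5% of genes shift by over 1 on the log2 scale against pairs 2 and 3 (SD of the shift 1.55), where pair 2 against pair 3 gives 2.57% (SD 0.38). Values argue against a swap of knockdown and control in pair 1, as DAXX there differs by -1.60. The labelling or hybridisation of slide 1 may account for the shift, since 2 probes of the same gene shifted with a correlation of 0.418 (95% interval 0.389 to 0.446) over 4104 genes, below the 0.5 set as its bound, although GFP minus luciferase controls 2 and 3 gave only 0.547, so the test is not specific to slide 1. Cells of another type stay open: the median shifts were 0.99, 1.03 and 1.22 for fibroblast, blood and keratin-rich markers, of which 10, 9 and 16 passed the filter in these cells, and 23.2%, 15.4% and 11% of 10000 random lists matched on signal shifted as much. The random lists themselves rose, with median shifts of 0.58, 0.32 and 0.55 in the same order. The knockdown was not tested as a source of this shift, as both groups have an array in pair 1.

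The p53 targets and immediate early genes were higher after Daxx knockdown at the preset correlation, but not past the threshold with an estimated one (adjusted p = 0.0737 and 0.336). A constant per array cancels from the excess of both lists over all genes, so scaling by the 75th percentile or the median gave 0.307 by construction and tests nothing. Quantile normalization (0.305) and normexp background correction (0.266 on the log2 scale) could have changed the excess, and neither removed it. Daxx pair 1 alone is argued against by an excess of 0.191 without it (0.400, 0.370 and 0.139 by pair). The luciferase control is also an shRNA plasmid, so an interferon response stays open only as far as it goes beyond that of the control. The interferon-stimulated genes had a median excess of 0.00869 (95% interval -0.166 to 0.149), but 17 were higher and 16 lower with an SD of 0.51. ISG20 at 0.61 goes with such a response, where IFIT1 at -0.44 and DDX60 at -0.42 go against it. The bound set for excluding it is met only if CXCL10, not well above background on any luciferase array, is left out (excess -0.01, SD 0.29). Among the 10 splits of the 6 arrays the real split had 5 lists past the threshold, 8 of the 10 splits had as many, and the highest other had 9. The number of lists past the threshold at the preset correlation thus does not set the real grouping apart from other groupings. With 10 splits no share under 0.05 could be reached in any case. A response to loss of Daxx or another effect of the hairpin may each be the source, and another hairpin was not analysed here.

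Markers of fibroblasts were higher after HOTAIR knockdown at the preset correlation, but not past the threshold with an estimated one (adjusted p = 0.501). Genes of like signal did not rise as a whole, as 10000 random lists matched on signal had a median of -0.02. Of these lists 1.41% had as high a median as the markers. That share decides nothing, since the markers were taken up after passing in these same data and the random lists draw genes independently. Among genes well above background on all 12 arrays the list's median fell to 0.12 (adjusted p = 0.168). Fibroblasts in the cultures stay open as a possible source: COL1A2, among their most abundant transcripts, was well above background on 0 HOTAIR siRNA arrays, with a difference of 0.11 near background that decides nothing, and COL1A1, FBLN1 and FBLN2 after HOTAIR knockdown, at -0.00, -0.09 and -0.12, were not higher but start from levels of -2.31, 2.56 and -2.54, against -6.50 for COL6A3, that could hide a small share. Among the splits the real one had 3 lists past the threshold, 9 of the 10 splits had as many, and the highest other had 10. Here too the number of lists at the preset correlation does not set the real grouping apart, and a share under 0.05 could not be reached. A response to loss of HOTAIR stays among the open explanations, untested.

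For counts of genes by limma, the real split gave 0 in the Daxx experiment (574 at an unadjusted p under 0.05, 3952 with the replicate block), 10 of the 10 splits gave as many, and the highest other gave 8882. That split and 3 others that follow the slide, with 3, 3 and 4 genes, group both arrays of slide 1 with 1 of slide 2 against the other 3 of slide 2, so that the count points to a structure of the samples that follows the slide. With the slide as a block the real split gave 17 genes. In the HOTAIR experiment the real split gave 0 (441 at an unadjusted p under 0.05), 10 of the 10 splits gave as many, and the highest other gave 0. These splits are too few for a share under 0.05. For the difference of the responses all 100 pairs of splits gave as many as the real 0 (522 at an unadjusted p under 0.05). Every split gives at least 0 genes, so none of these 3 counts says anything about chance. The size of the correlation of the responses, 0.0891, was reached by 69 of the 100, with 0.425 as the highest other, so chance cannot be excluded there. Many of these splits mix arrays of different pairs and slides, and the correlation was not tested by splits within pairs. Among splits that part all 3 pairs, with the replicate block, 3952 genes had an unadjusted p under 0.05 in the real Daxx split against 1909, 853 and 738 in the others, and 3821 in the real HOTAIR split against 986, 421 and 1088. By lists past the threshold the same splits gave 6 for Daxx against 9, 3 and 3, and 3 for HOTAIR against 8, 4 and 7. In each of the others, knockdown and control are exchanged in 1 pair.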

How the results depend on the processing

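The tests without Daxx pair 1, with the replicate block and trend and robust together, with the replicate block at an adjusted p under 0.1, and with gene-by-gene array weights were chosen after the result was seen. The DAXX level after Daxx knockdown and the HOTAIR level after HOTAIR knockdown were lower under each of 22 settings. DAXX stayed short of the threshold in 19 and HOTAIR in 18, and passed with array weights (-1.12, adjusted p = 0.00986, and -1.16, adjusted p = 0.00108), with the slide as a block (-1.31, 0.0457, and -1.25, 0.0384) and with the replicate block, trend and robust (-1.31, 0.0151, and -1.25, 0.00711). The HOTAIR level after HOTAIR knockdown also passed with gene-by-gene weights (-1.16, adjusted p = 0.00181). The planned array weights stopped before converging, with luciferase replicate 2 weighted 246 and the other arrays 0.0424 to 4.56. They gave 727 genes changed by Daxx knockdown, 752 genes changed by HOTAIR knockdown, 600 genes whose response differs between the knockdowns, 54 in both and 5 HOTAIR lists. Gene-by-gene weights gave 1 gene for Daxx (CXCL10) and 685 for HOTAIR. The slide as a block gave 17 and 5 genes, the replicate block 2 for HOTAIR, and at an adjusted p under 0.1 it gave 28 for HOTAIR and 34 for the difference. The replicate block with trend and robust gave 339, 6 and 121 genes. Leaving out Daxx pair 1 gave 1 gene for Daxx (CXCL10). The cause was not tested. Beyond the S phase genes after Daxx knockdown and, for the difference, heat shock, neuronal and adrenal lineage and unfolded protein response genes, the replicate block changed no other call of a list or a target. Camera with an estimated correlation and fry each gave 0 lists for Daxx (smallest adjusted p 0.0737 and 0.110) and 0 for HOTAIR (0.240 and 0.576). Normexp and quantile normalization each gave 8 Daxx lists. Of 84 single genes followed through the settings, PHF19 after HOTAIR knockdown reversed to -0.067 with the mean over probes. The others kept their direction, as did the 8 lists that passed, and genes named after their values were seen were not followed. Scalings put the median of all genes between -0.05 and 0.04.

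Leaving out each array in turn, where the groups left with 2 arrays share the spread of all groups, gave DAXX differences of -1.61 to -0.85 and HOTAIR differences of -1.31 to -1.19. Daxx genes numbered 0 to 1 (CXCL10 without luciferase replicate 1), HOTAIR genes 0 to 3 and genes of the difference 0 to 2 (both without HOTAIR siRNA replicate 3). Daxx lists numbered 3 to 10, with 3 without Daxx replicate 2, 8 without luciferase replicate 3, 9 without Daxx replicate 1 and 10 without Daxx replicate 3. HOTAIR lists numbered 1 to 7, with 1 without GFP replicate 2, GFP replicate 3 or HOTAIR siRNA replicate 3, 5 without HOTAIR siRNA replicate 2, 6 without GFP replicate 1 and 7 without HOTAIR siRNA replicate 1. The correlation of the responses ranged from -0.20 without luciferase replicate 1 to 0.11 without Daxx replicate 1, with -0.19 without Daxx replicate 2, and was reversed to 0.11, 0.02 and 0.10 without Daxx replicate 1, luciferase replicate 2 and luciferase replicate 3. The cause was not tested. Signal over background limits genes such as CXCL10, DQX1, TNMD and DIRC3, which were not well above background on any control array of their comparison.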

Other observations

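The values in this part, from a comparison and a count of spots that were not planned, were chosen after the result was seen. The controls of the experiments differed from each other: between GFP siRNA and luciferase shRNA, limma called 1591 genes, 928 higher with GFP siRNA and 663 lower. These arrays lie on different slides, so delivery and slide cannot be told apart.

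Spots far below the other group, by over 2 on the log2 scale below the lowest of its 3 arrays where those were well above background, gathered in 1 of the 164 columns on HOTAIR siRNA arrays 1 and 2. On array 1, 14 of the 38 such spots lay in column 110, among 256 spots compared there, and the next column, 19, held 10. On array 2, 21 of the 23 lay in column 110, among 247 compared, and the next column held 1. On array 3, 6 of 11 lay in column 70. On each of the other arrays no column held more than 2. Genes with a spot in column 110 include UBR4, at -5.52, -8.20 and 1.80 on HOTAIR siRNA arrays 1, 2 and 3, B3GALT6, at -3.93, -3.47 and 0.95, and DDX54, at -1.02, -1.42 and 1.04. KCND1 was at -7.37, -8.21 and -6.06. RAB7A was at -3.41, -3.03 and 2.58 in column 110, and its spot in column 19 was at -9.56 on array 1 and 2.70 on array 2. Another probe of DDX54 was at -2.30 and -2.09 on HOTAIR siRNA arrays 1 and 2 and at -2.31, -1.98 and -1.97 on the GFP arrays. None of these spots was marked as an outlier by the software.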
